A study of Homo sapiens with 8 samples.

How the data were processed

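Total RNA was extracted from 8 SkMel147 tumours, 4 of vehicle-treated and 4 of doxycycline-treated mice, and each was hybridised to 1 Affymetrix array, per the labels. The deposited table holds log2 values made by RMA, per the submitters' processing notes. RMA subtracts background, quantile-normalises the probes across arrays and summarises them to 1 value per row. The software and version used, the array's probe definition and any filter are not given in the sources used here. RMA forces the arrays to similar distributions, so a shift of most transcripts in 1 direction would be partly removed and would appear as a spread of changes in both directions. The values are not centred per gene. No scanner values were used here, so how far each probe lay above background is unknown, and changes of dim genes may be understated.

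The table has 18569 rows. The platform annotation pairs 17511 rows with 1 gene symbol and none with several, and 1058 rows had no gene name here and were left out of the named results. All of the gene identifiers were found in the RefSeq gene table used for names, with the same symbols. For 17 genes with more than 1 row, the row with the highest mean over all arrays was kept, which left 17492 genes. No filter on dim genes and no further normalization were applied. No columns other than the 8 arrays were present, and no coordinates are given because no genome build is named.

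Groups and replicate numbers come from the sample titles. Doxycycline was compared with vehicle using limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Log2 fold changes are doxycycline minus vehicle, and SE is limma's moderated standard error. Gene lists, 34 in all, of which 7 hold markers of other cell types, were fixed before the data were examined. The list of mitochondrially encoded genes had 0 measured members and was not tested, and 130 of the 916 list members were not measured here. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists tested. Beside that, camera with a correlation estimated for each list, the rotation test fry, and an exact two-sided permutation test of each list's mean per array over the 4 and 4 arrays were run. The fry test asks whether a list's genes move, on balance, one way and does not compare them with other genes. Calls of list members are given over all genes and adjusted over the list alone.

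The rule for named genes, also fixed before the data were examined, took the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, the 3 members with the smallest p in the list's direction from each list past the threshold, the measured members of the MYC network, and the 2 brightest members of each marker list. Genes outside the rule are said to be named after their values were seen. The alternatives were quantile normalization on top, centring each array on its median or on the ribosomal protein genes, leaving out the dimmest 40% of genes, a trended and robust prior, array weights, the replicate number as a block, the mean of all rows of a gene, all rows tested alone, a fold of at least 1.5, and leaving out each array in turn. Leaving out vehicle replicate 2 and doxycycline replicate 1 together, the arrays of each group with the lowest array weight (0.502 and 0.728), was added after seeing the data.

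The procedure was tested on simulated data for the comparison of doxycycline with vehicle over 17492 genes with 200 genes changed by known amounts. It recovered 47% of genes changed by 1 and 81% of those changed by 2 on the log2 scale, with 0 of the wrong sign. The share of false calls was 7.91%, above the nominal level, from 11 false calls in a single simulated set. Far more genes, 1884, were called in the data than were changed in the simulation. The adjusted threshold is stricter when fewer genes change, so these rates need not hold for the data. Of the lists left unshifted in the simulation, 1 was called by camera. The simulated genes were drawn independently, so this does not measure false calls of lists whose genes vary together. In the data the estimated correlation reached 0.83, in the type I interferon list. Figures were drawn in Python 3.11.15.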

Results

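Gene expression was measured in 8 tumours grown under the skin of BALB/c nude mice from SkMel147, an established human melanoma cell line. Doxycycline was given in the drinking water to induce Omomyc in the tumour cells, and 4 tumours of doxycycline-treated mice were compared with 4 of mice given the vehicle. Induction of the transgene was not measured directly here. Omomyc is an engineered fragment of MYC that carries the dimerisation and DNA-binding end of the protein and competes with MYC for its partners and DNA sites. Treatment started when tumours measured 100 mm3 and lasted 7 days. Each tumour gave 1 Affymetrix array. The 8 arrays had medians between 5.02 and 5.13 (log2), and no pair of arrays held identical values. Arrays of the same group correlated at 0.961 to 0.982 and arrays of different groups at 0.933 to 0.955, across genes, which are not independent replicates. The first principal component, with 42.7% of the variance, separated the groups. Vehicle replicate 2 stood apart from the other vehicle arrays on the second component (16.0%), together with doxycycline replicate 4, and doxycycline replicate 1 stood apart on the third (12.3%). The lower quartile was 3.20 in vehicle replicate 2 and 3.23 in doxycycline replicate 4, and 3.03 to 3.10 in the others. Their upper quartiles were 6.72 and 6.79, against 6.86 to 6.92. Deviations of these arrays from their group means correlated at 0.23, the highest of any vehicle and doxycycline pair. What they share was not tested. The array is made for human sequences, so RNA of the mouse host can only cross-hybridise to it. With 4 arrays per group, the number of arrays limits the precision.

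The transcript of MYC itself was read first, because the induced transgene contains part of it. MYC averaged 5.63 ± 0.34 (SD, n = 4) in vehicle tumours and 6.81 ± 0.96 (SD, n = 4) in doxycycline tumours, in log2 units. The difference of 1.18 ± 0.41 (SE) did not pass limma's test over all genes (adjusted p = 0.0987). Of the doxycycline arrays, 3 lay above every vehicle array, and doxycycline replicate 1, at 5.49, lay within the vehicle range of 5.26 to 5.92. Without that array the difference was 1.62 and passed (limma, adjusted p = 0.0054). The probes for MYC may also detect the transgene, so this value checks the labels only in part. Of the 13 measured genes of the MYC network, the partners and antagonists of MYC, MXI1 fell by 0.70 ± 0.16 (SE) and MGA fell by 1.24 ± 0.29 (SE), with limma adjusted p of 0.0163 and 0.0205. MAX, the obligate partner of MYC, differed by 0.54 ± 0.17 (SE), which did not pass (limma, adjusted p = 0.0693). It passed with arrays centred on ribosomal protein genes, without the dimmest genes, with a trended and robust prior, with array weights and without vehicle replicate 2 (adjusted p of 0.0200, 0.0306, 0.0125, 0.0326 and 0.0384). ZBTB17 and MLXIP did not pass either. ZBTB17 passed as a fall without the dimmest genes (limma adjusted p = 0.0283), and MLXIP as a fall without doxycycline replicate 1 (0.0439). Adjusted over the list alone, 2 network genes rose and 3 fell, and the list as a whole did not pass camera (adjusted p = 0.358). The calls of MXI1 and MGA ended with arrays centred on ribosomal protein genes (adjusted p of 0.132 and 0.0507, at -0.45 and -0.99), with the replicate number as a block (0.0720 and 0.0568) and without vehicle replicate 4 (0.0509 and 0.0572), and that of MGA also without vehicle replicate 3 or doxycycline replicate 4 (adjusted p of 0.0651 and 0.0507).

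The question of the comparison was what Omomyc changes in melanomas growing in mice. All 40 measured mitotic genes and 31 of 39 genes of DNA replication and S phase fell in doxycycline tumours, and 12 of 25 lysosomal genes rose, lists that held with an estimated correlation (adjusted p = 0.0391 for each). In the type I interferon list 32 of 38 genes rose, with adjusted p = 0.269 for the list with an estimated correlation. Of 17492 genes tested, 1884 (10.8%) passed limma at an adjusted p under 0.05, of which 830 rose and 1054 fell. Of the called genes, 1165 changed by at least 2-fold, 436 upward and 729 downward. Without regard to the threshold, all 4 doxycycline arrays lay above, or all below, all 4 vehicle arrays for 3095 genes (17.7%), where chance gives 2.86%. The split between directions changed most with centring on the ribosomal protein genes. The share that fell was 55.9% as deposited, 57.1% with quantile normalization on top and 51.2% with each array centred on its median. The ribosomal protein list itself had a median of -0.26, so centring on it moves every gene upward. When each array was centred on the ribosomal protein genes, the median of all genes moved from 0.04 to 0.28, 1872 genes rose and 692 fell, and the share that fell went from 55.9% to 27.0%. With 1 tumour left out, the number called was between 1252 (without vehicle replicate 3) and 1760 (without vehicle replicate 2).

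Of the 12 largest rises among called genes whose groups do not overlap, 5 were members of the type I interferon list. CHRNA1, a subunit of the muscle acetylcholine receptor, rose 15.5-fold, from 5.11 ± 1.07 to 9.06 ± 1.13 (SD, n = 4). IL10, an anti-inflammatory cytokine, rose 11.8-fold, and TNFSF10, the death receptor ligand TRAIL, rose 11.1-fold with log2 fold change 3.48 ± 0.50 (SE; limma adjusted p = 0.00135). The interferon-induced genes BST2, RSAD2, IFIT2, IFI44L and IFIT1 rose by 12.1-fold, 9.34-fold, 8.73-fold, 7.88-fold and 7.69-fold. The remaining rises were those of MEST (10.1-fold), PLXDC2 (9.71-fold), the organic anion exporter ABCC3 (8.91-fold) and KLRC3 (8.04-fold), a natural killer cell receptor gene whose probes may share sequence with its near-identical neighbour KLRC2. BST2 lost its call with a trended and robust prior (limma adjusted p = 0.0687) and without vehicle replicate 3, doxycycline replicate 1 or doxycycline replicate 2 (adjusted p of 0.0685, 0.0531 and 0.0573), and KLRC3 lost its call without doxycycline replicate 2 (adjusted p = 0.0501). Leaving out single tumours moved some of these folds, before the log2, by over 1.5 times. On the log2 scale BST2, at 3.59, was 2.85, 4.24 and 4.20 without vehicle replicate 1, 2 or 4. RSAD2, at 3.22, was 3.90 without vehicle replicate 2, and IL10, at 3.56, was 2.92 without doxycycline replicate 3. KLRC3, at 3.01, was 2.37 and 3.64 without doxycycline replicate 1 or 3. Without vehicle replicate 2 and doxycycline replicate 1 together, CHRNA1, ABCC3 and KLRC3 were at 2.91, 3.89 and 1.99.

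The 12 largest falls by the same rule included IL1B and the chemokines CXCL8 and CXCL5. IL1B, interleukin 1 beta, was 36.6-fold lower with doxycycline, from 10.73 ± 1.07 to 5.54 ± 3.08 (SD, n = 4), and doxycycline replicate 4, at 9.67, lay close to the lowest vehicle array. CXCL8 was 21.1-fold lower and CXCL5 11.4-fold lower, with log2 fold changes of -4.40 ± 0.72 and -3.52 ± 0.33 (SE; limma adjusted p of 0.00301 and 0.000135). TMEM97, the sigma-2 receptor, fell 21.3-fold, IGFBP3, a binding protein of insulin-like growth factors, 16.4-fold, and the anion transporter SLCO4A1 16.4-fold. The smallest adjusted p of any gene, 1.29e-05, was shared by these 3 genes, PAICS and SMS, the spermine synthase gene, named here after its value was seen. Other falls were those of the lipoprotein receptor LRP8 (12.7-fold), the interstitial collagenase MMP1 (12.3-fold), the signalling adaptor TRAF3 (10.9-fold) and the kinetochore gene NUF2 (10.7-fold). GTF3A, the transcription factor of the 5S ribosomal RNA genes, and TXNL4A, a component of the spliceosome, fell by 3.56 ± 0.24 and by 3.68 ± 0.24 (SE) on the log2 scale. IL1B lost its call with a trended and robust prior (limma adjusted p = 0.0921) and without vehicle replicate 2, vehicle replicate 4 or doxycycline replicate 3 (adjusted p of 0.0578, 0.0516 and 0.0570). Its log2 fold change of -5.19 was -4.09 without doxycycline replicate 2 and -6.57 without doxycycline replicate 4, and that of CXCL8 was -5.25 without doxycycline replicate 4. MMP1, at -3.62, lost its call with the trended and robust prior (adjusted p = 0.0625) and was at -2.91 without vehicle replicate 2 and -4.29 without doxycycline replicate 4. Without vehicle replicate 2 and doxycycline replicate 1 together, MMP1 was at -2.45 and IL1B lost its call (adjusted p = 0.0978).

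**Figure D1:**
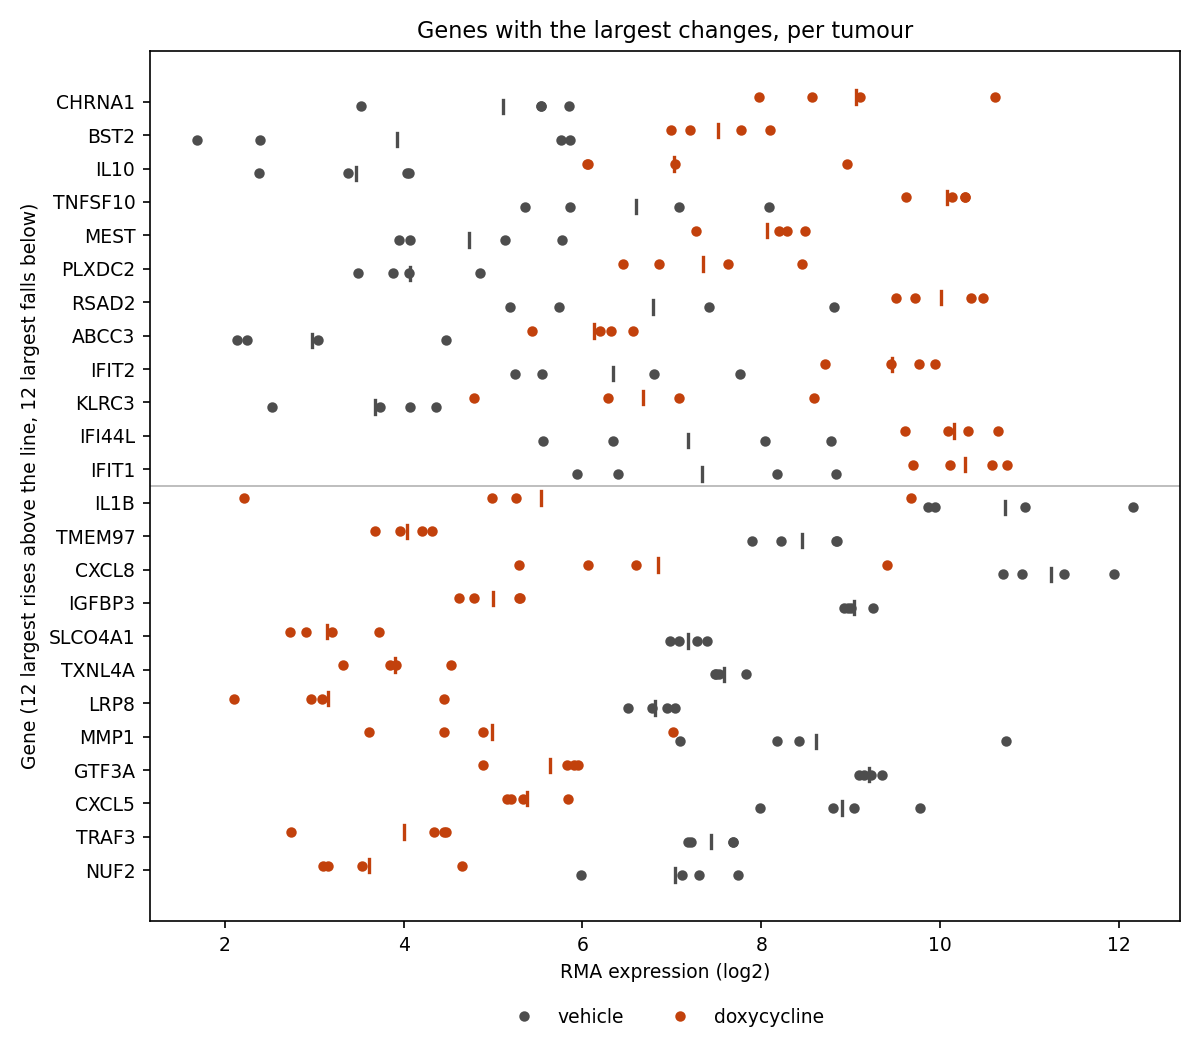
RMA expression (log2, horizontal axis) of the 12 genes with the largest rises and the 12 with the largest falls among called genes whose groups do not overlap (vertical axis). Each point is 1 tumour, dark grey for vehicle and orange for doxycycline, and each tick is a group mean; the doxycycline tumours are widest apart for IL1B, where 1 of them lies at 9.67.

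Of all lists, the mitotic genes had the lowest median. All 40 measured mitotic genes fell, over all genes and adjusted over the list alone, with a median log2 fold change of -2.48, or 5.57-fold lower. Examples are the chromosome motors KIF4A (-3.00 ± 0.18, SE) and KIF2C (-2.80 ± 0.20, SE) and the spindle checkpoint gene MAD2L1 (-2.52 ± 0.18, SE). Of 39 DNA replication and S-phase genes, 31 fell and none rose (34 adjusted over the list alone), with a median of -1.29. RRM2, a subunit of ribonucleotide reductase, fell by 3.28 ± 0.20 (SE), UHRF1, which maintains DNA methylation, fell by 2.30 ± 0.18 (SE) and thymidylate synthase, TYMS, fell by 1.94 ± 0.19 (SE). Both lists passed camera (adjusted p of 2.5e-52 and 2.4e-27), and both held with an estimated correlation (adjusted p = 0.0391 for each). The mean of the mitotic list was 7.66 ± 0.32 in vehicle and 5.26 ± 0.05 in doxycycline tumours (SD, n = 4; exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give).

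Of 22 genes of nucleotide biosynthesis, 10 fell and none rose (14 adjusted over the list alone), with a median of -0.68. PAICS and PPAT, enzymes of purine synthesis, fell by 3.23 ± 0.18 and by 2.42 ± 0.17 (SE), and MTHFD2 of the mitochondrial folate pathway fell by 2.22 ± 0.21 (SE). Of 18 glycolysis genes, 9 fell and none rose (12 adjusted over the list alone), with a median of -0.77. Among them were the glucose transporter SLC2A1 (-1.64 ± 0.19, SE), PFKL (-1.88 ± 0.24, SE) and PFKFB3 (-1.60 ± 0.23, SE), which act at the phosphofructokinase step. Camera called both lists (adjusted p of 3.2e-12 and 3.7e-10), and neither call held with an estimated correlation (adjusted p = 0.0553 and adjusted p = 0.0677 with an estimated correlation).

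Most members of the lists of canonical MYC targets, ribosome production and translation did not pass, although the list means fell. The means of the MYC target, ribosomal RNA and translation lists lay below every vehicle tumour in all 4 doxycycline tumours (exact two-sided permutation p = 0.0286 for each). That of the cytosolic ribosomal proteins did in 3 of 4 (exact p = 0.0571). For comparison with the counts below, 1054 of all 17492 genes tested fell. Of 45 measured MYC targets, 14 fell and none rose (16 adjusted over the list alone), with a median of -0.45. TMEM97 (-4.41 ± 0.25, SE), the mitochondrial chaperone HSPD1 (-2.50 ± 0.20, SE) and the nucleolar methyltransferase FBL (-2.31 ± 0.19, SE) led the list. Of 41 genes of ribosomal RNA processing and RNA polymerase I, 9 fell (10 adjusted over the list alone), with NAT10 (-2.14 ± 0.33, SE), POLR1B (-0.86 ± 0.21, SE) and POLR1E (-0.76 ± 0.19, SE) in front. Of 42 cytosolic ribosomal protein genes, RPL10A and RPL19 fell, by 0.90 ± 0.21 and by 0.63 ± 0.18 (SE), and 1 did adjusted over the list alone. RPL14, at -0.51 ± 0.16 (SE), did not pass (limma adjusted p = 0.0710), but did without the dimmest genes and with a trended and robust prior (0.0302 and 0.00321). Of 27 genes of translation and tRNA charging, the elongation factor gene EEF1D (-1.30 ± 0.17, SE), the initiation factor gene EIF1AX (-1.31 ± 0.20, SE) and IARS1 (-1.70 ± 0.36, SE) fell, 3 over all genes and 3 adjusted over the list alone. The 4 lists passed camera (adjusted p of 3.8e-08, 1.7e-05, 0.000111 and 0.000118). With an estimated correlation the calls were lost, at adjusted p = 0.0677, adjusted p = 0.271, adjusted p = 0.520 and adjusted p = 0.269. With arrays centred on ribosomal protein genes, the list medians were -0.21, -0.06, -0.02 and -0.06 and that of all genes 0.28, a shift that is alike for every gene of an array. With 1 tumour left out, RPL19, POLR1B and POLR1E lost their calls in 7, 6 and 5 of 8 fits (limma adjusted p up to 0.126, 0.0704 and 0.0786), and RPL10A lost it without vehicle replicate 1 (adjusted p = 0.0532). RPL19, POLR1B and POLR1E also lost their calls with arrays centred on ribosomal protein genes (adjusted p of 0.165, 0.0942 and 0.112) and with the replicate number as a block (0.115, 0.0641 and 0.0903), and RPL19 with array weights (0.0526) and with arrays centred on their medians (0.0584). Without vehicle replicate 2 and doxycycline replicate 1 together, RPL19 and POLR1B lost theirs (0.129 and 0.0625).

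Of 36 mitochondrial ribosomal protein genes, 7 fell and none rose (9 fell and 1 rose adjusted over the list alone), with a median of -0.21. MRPL15, MRPL3 and MRPS2 fell by 1.20 ± 0.19, by 1.00 ± 0.16 and by 0.90 ± 0.18 (SE). Of 34 nuclear-encoded genes of oxidative phosphorylation, COX5A and UQCRB fell, by 0.63 ± 0.17 and by 0.72 ± 0.20 (SE), with a list median of -0.18 and 0 members called adjusted over the list alone. CYCS was at -0.71 ± 0.22 (SE) and did not pass (limma adjusted p = 0.0622), but did with quantile normalization, without the dimmest genes, with a trended and robust prior, with array weights and without vehicle replicate 2 (adjusted p of 0.0359, 0.0332, 0.0200, 0.0381 and 0.0328). The lists passed camera (adjusted p of 6.4e-05 and 0.0122) but not with an estimated correlation (adjusted p = 0.278 and adjusted p = 0.214 with an estimated correlation). Both medians turned to 0.04 and 0.06 with arrays centred on ribosomal protein genes, where the median of all genes was 0.28, and the oxidative phosphorylation list lost its call there (adjusted p = 0.101). With 1 tumour left out, COX5A and UQCRB lost their calls in 6 and 7 of 8 fits (limma adjusted p up to 0.104 and 0.102), and both did with arrays centred on ribosomal protein genes (0.156 and 0.157) and with the replicate number as a block (0.115 and 0.104), and COX5A without vehicle replicate 2 and doxycycline replicate 1 together (0.0841).

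Of 21 genes of cholesterol and fatty acid synthesis, 13 fell and 1 rose (17 and 1 adjusted over the list alone), with a median of -1.03. SQLE and HMGCS1, enzymes of cholesterol synthesis, fell by 1.88 ± 0.22 and by 1.58 ± 0.21 (SE), and INSIG1, which the sterol regulators induce, fell by 1.92 ± 0.28 (SE). SREBF1, a transcription factor of lipid synthesis, was the gene that rose, by 0.93 (limma adjusted p = 0.00821), and was picked out after its value was seen. Of 21 hypoxia genes, 8 fell and none rose (12 fell and 3 rose adjusted over the list alone), with a median of -0.55. The angiogenic factor VEGFA (-2.40 ± 0.19, SE), NDRG1 (-2.69 ± 0.22, SE) and AK4 (-2.46 ± 0.20, SE) led it. Of 24 targets of ATF4, the transcription factor of the amino acid stress response, 4 fell and none rose, also adjusted over the list alone. They included the hormone gene STC2 (-2.11 ± 0.22, SE), the serine synthesis enzyme PSAT1 (-2.30 ± 0.35, SE) and the amino acid transporter SLC7A5 (-2.39 ± 0.41, SE). Camera gave adjusted p of 7.8e-12, 2.4e-07 and 0.00474 for the lists. None held with an estimated correlation (adjusted p = 0.130, adjusted p = 0.0677 and adjusted p = 0.269 with an estimated correlation).

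Of 38 measured type I interferon genes, 32 rose and none fell (36 adjusted over the list alone), with a median log2 fold change of 1.82, or 3.52-fold higher. MX2 (1.58 ± 0.23, SE), HERC6 (1.88 ± 0.30, SE) and IFIT2 (3.13 ± 0.50, SE) had the smallest p-values. The list mean was 6.70 ± 0.95 in vehicle and 8.64 ± 0.40 in doxycycline tumours (SD, n = 4; exact two-sided permutation p = 0.0286). Vehicle tumours differed widely, with vehicle replicates 1 and 3 at 5.93 and 5.88 and vehicle replicates 2 and 4 at 7.78 and 7.22. Of 19 genes of antigen presentation, 5 rose and none fell (10 rose and 1 fell adjusted over the list alone), with a median of 0.50. They included TAPBP (1.40 ± 0.18, SE) and ERAP2 (0.84 ± 0.17, SE), which load and trim peptides, and the class I molecule HLA-E (1.03 ± 0.19, SE). Both lists passed camera (adjusted p of 1.4e-20 and 0.0107), and neither with an estimated correlation (adjusted p = 0.269 and adjusted p = 0.498 with an estimated correlation). The antigen presentation list lost its call with arrays centred on ribosomal protein genes (adjusted p = 0.0611, median 0.75) and without doxycycline replicate 3 (adjusted p = 0.0568, median 0.51), although its median did not shrink. Beside these lists, the mean of 20 leukocyte markers differed by 0.29 between groups, and vehicle replicate 2 had the highest mean of the vehicle tumours in the interferon, antigen presentation and leukocyte lists.

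Of 21 measured NF-kB and cytokine genes, 10 fell and none rose (13 adjusted over the list alone), with a median of -1.49. NFKB1, the gene of an NF-kB subunit, fell by 1.64 ± 0.24 (SE), CXCL8 fell by 4.40 ± 0.72 (SE) and IL1A fell by 2.35 ± 0.39 (SE). The list passed camera (adjusted p = 3.1e-08) but not with an estimated correlation (adjusted p = 0.270 with an estimated correlation). Its mean was 7.77 ± 0.84 in vehicle and 6.30 ± 0.57 in doxycycline tumours (SD, n = 4; exact two-sided permutation p = 0.0571). Doxycycline replicate 4, at 7.09, lay just above vehicle replicate 1, at 7.08. Vehicle replicate 2 was the highest, at 8.96, with the other vehicle tumours at 7.08 to 7.75. The median was -1.16 without doxycycline replicate 1 and -0.95 without vehicle replicate 2 and doxycycline replicate 1 together.

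Of 25 genes of lysosome and autophagy, 12 rose and none fell (13 adjusted over the list alone), with a median of 0.52. HEXA and CTSA, lysosomal hydrolases, rose by 1.38 ± 0.19 and 1.21 ± 0.18 (SE), and ATP6AP1, an accessory gene of the proton pump, rose by 1.26 ± 0.19 (SE). Of 26 matrix genes, 12 rose and 1 fell (14 and 2 adjusted over the list alone), with a median of 0.76. Fibronectin, FN1 (2.83-fold), fibrillin 1, FBN1 (1.62 ± 0.22, SE), and the protease inhibitor TIMP1 (1.24 ± 0.19, SE) had the smallest p-values, and the gene that fell was MMP1 (-3.62 ± 0.80, SE). Camera called both lists (adjusted p of 4.6e-09 and 6.1e-05). The lysosome list held with an estimated correlation (adjusted p = 0.0391) and the matrix list did not (adjusted p = 0.130 with an estimated correlation).

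Of 19 genes of the endoplasmic reticulum stress response, HERPUD1 (0.92 ± 0.20, SE), SEL1L (0.76 ± 0.17, SE) and SYVN1 (1.01 ± 0.23, SE) rose and none fell (6 rose adjusted over the list alone); these genes act in the removal of misfolded proteins. Of 22 p53 targets, SESN1 (1.16 ± 0.24, SE), ZMAT3 (1.13 ± 0.24, SE) and the death receptor FAS (0.87 ± 0.22, SE) rose and 1 gene, AEN, fell by 1.35 (5 rose and 2 fell adjusted over the list alone). Camera gave adjusted p of 0.0206 and 0.0235, and with an estimated correlation adjusted p = 0.271 and adjusted p = 0.523. The stress list lost its call without doxycycline replicate 3 (adjusted p = 0.0526, median 0.25 against 0.24), and the p53 list without doxycycline replicate 2 (adjusted p = 0.194, median 0.16 against 0.31). SEL1L lost its call without vehicle replicate 3 (limma adjusted p = 0.0548), and HERPUD1 and SEL1L without vehicle replicate 2 and doxycycline replicate 1 together (adjusted p of 0.0580 and 0.0552). FAS lost its call in 6 of 8 fits with 1 tumour left out (adjusted p up to 0.0798) and with the replicate number as a block (adjusted p = 0.0641).

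Markers of other cell types of the tumour were measured on the same arrays. Of 13 fibroblast and pericyte markers, the matrix protein gene POSTN (3.57 ± 0.79, SE), the growth factor receptor PDGFRA (2.51 ± 0.56, SE) and TAGLN (1.17 ± 0.27, SE) rose and none fell (5 rose adjusted over the list alone). The list passed camera (adjusted p = 0.0196) but not with an estimated correlation (adjusted p = 0.270 with an estimated correlation), and lost its call without doxycycline replicate 4 (adjusted p = 0.0625, median 0.59 against 0.82). It kept its call at lower medians, 0.44 without doxycycline replicate 1, 0.52 without vehicle replicate 2, 0.46 with array weights and 0.46 without both of these tumours. POSTN, PDGFRA and TAGLN each lost their calls without vehicle replicate 1 (limma adjusted p of 0.0505, 0.0520 and 0.0535), POSTN and TAGLN also without vehicle replicate 3 (0.0538 and 0.0658), and TAGLN without doxycycline replicate 2 or 3 (0.0554 and 0.0583). Without vehicle replicate 4, POSTN and PDGFRA were at 4.37 and 3.10, and without vehicle replicate 2 and doxycycline replicate 1 together at 2.79 and 1.87, where both lost their calls (adjusted p of 0.0842 and 0.0755). The brightest markers of the list, FAP and LUM, differed by 0.37 ± 0.41 and 1.59 ± 0.51 (SE) and did not pass. LUM passed with arrays centred on ribosomal protein genes, without the dimmest genes and without vehicle replicate 4 (limma adjusted p of 0.0349, 0.0487 and 0.0149). Of 20 leukocyte markers, LYZ, the lysozyme gene, rose by 1.11 (limma adjusted p = 0.0102) and was picked out after its value was seen. The leukocyte list had a median of 0.28 and did not pass (adjusted p = 0.0847). It passed when vehicle replicate 2, doxycycline replicate 1 or doxycycline replicate 2 was left out (adjusted p of 0.0271, 0.0181 and 0.0357). The brightest leukocyte markers, CD68 and LAPTM5, were at 0.83 ± 0.31 and -0.47 ± 0.24 (SE), and the brightest endothelial markers, ENG and EGFL7, at -0.65 ± 0.19 and -0.07 ± 0.19 (SE); none passed. ENG passed as a fall with quantile normalization, without the dimmest genes, with a trended and robust prior and with array weights (limma adjusted p of 0.0401, 0.0284, 0.0122 and 0.0319), and CD68 as a rise with arrays centred on ribosomal protein genes (0.0471). In vehicle tumours, 5 of 15 endothelial, 0 of 11 keratinocyte, 2 of 15 muscle, 1 of 14 adipocyte and 1 of 8 erythroid markers lay above the median level of all genes. Mouse cells reach a human array only by cross-hybridisation, so a missing call of such dim markers does not show that the cells were unchanged. No endothelial, keratinocyte, muscle, adipocyte or erythroid marker passed the threshold, over all genes or adjusted over the list alone. None of these lists passed camera (adjusted p of 0.514, 0.276, 0.514, 0.785 and 0.844). Their brightest members were DSP and KRT5 of skin (1.36 ± 0.51 and 0.35 ± 0.20, SE), TPM2 and ACTA1 of muscle (-0.28 ± 0.19 and -0.08 ± 0.17, SE), PNPLA2 and DGAT2 of adipocytes (0.73 ± 0.25 and -0.18 ± 0.26, SE), and the haemoglobin genes HBA1 and HBB (0.11 ± 0.22 and 0.62 ± 0.27, SE). Without doxycycline replicate 4, DSP and PNPLA2 passed as rises (limma adjusted p of 0.0479 and 0.0460), PNPLA2 also with arrays centred on ribosomal protein genes (0.0416).

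**Figure D2:**
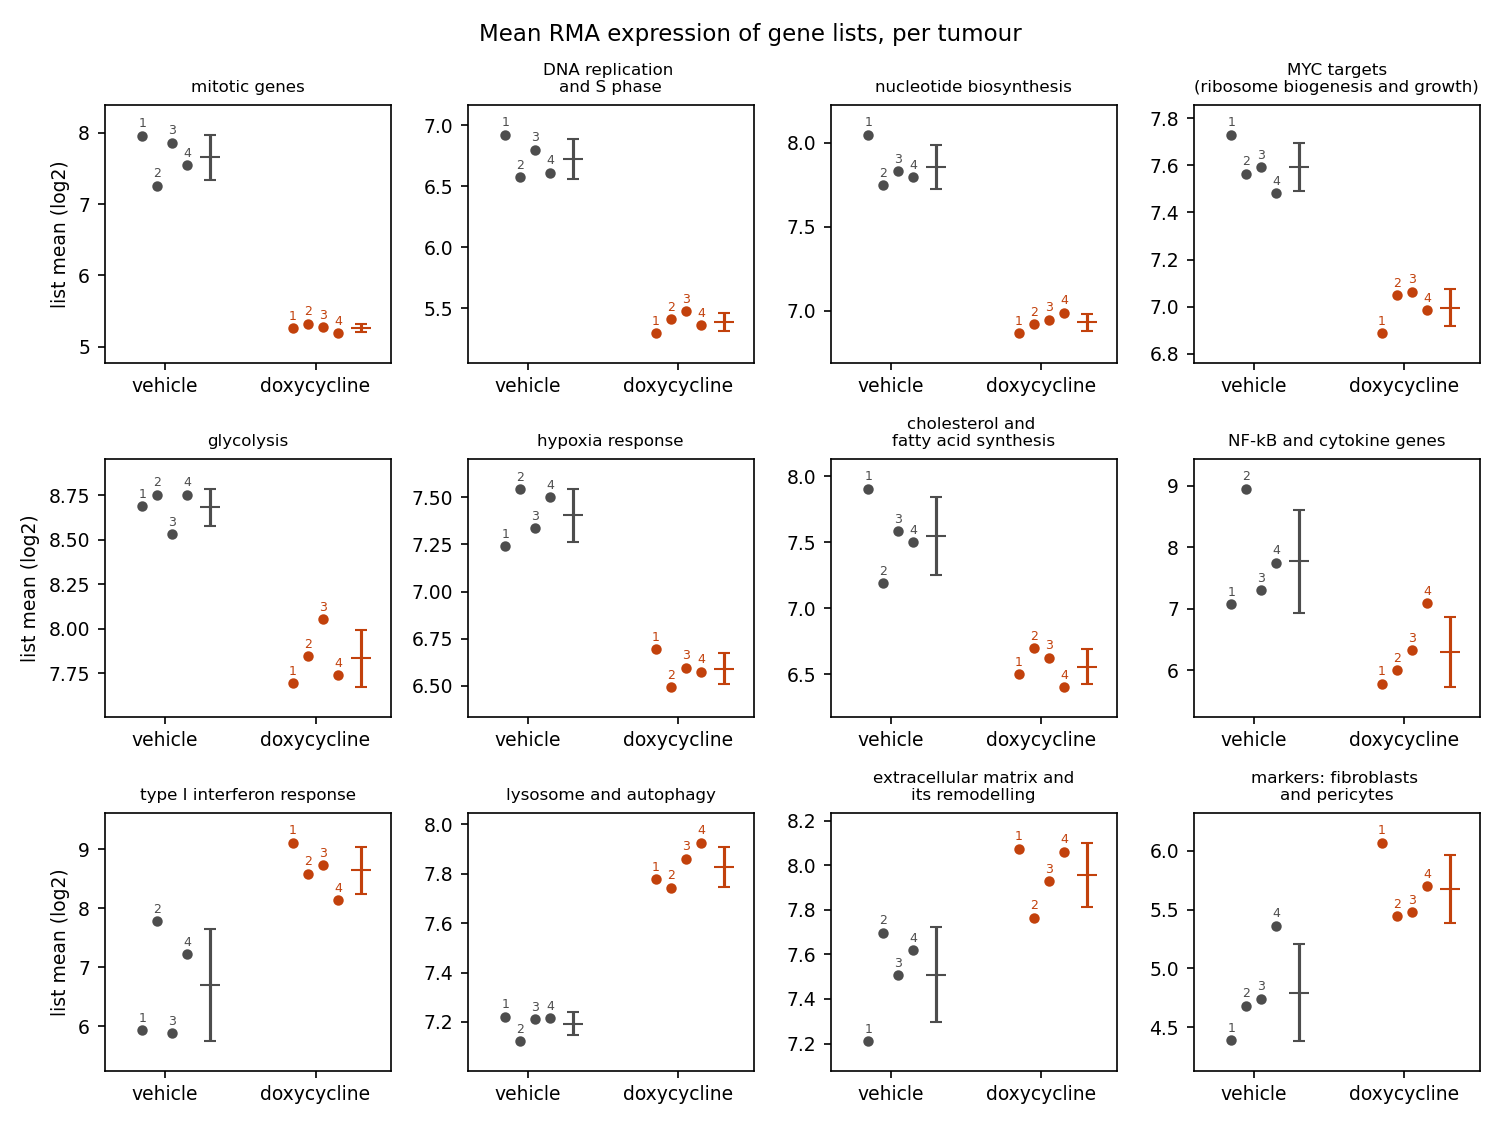
Mean RMA expression (log2, vertical axis) of 12 gene lists in each tumour, with the vehicle tumours in dark grey, the doxycycline tumours in orange and the replicate number above each point. Bars give the group mean ± SD (n = 4), and each panel has its own axis, which does not start at 0; the groups are apart in every panel but that of NF-kB and cytokine genes, where doxycycline replicate 4 (7.09) lies above vehicle replicate 1 (7.08).

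Of 22 genes of melanocyte differentiation, MLPH fell (-1.05, limma adjusted p = 0.0119), also adjusted over the list alone, and the list had a median of -0.08. Of 23 genes of undifferentiated and neural crest-like melanoma, NGFR (2.06), AQP1 (1.24) and THBS1 (1.26) rose and FOSL1 (-1.84) and TEAD4 (-1.85) fell, with 4 and 2 adjusted over the list alone and a median of 0.10. Of 19 genes of MAPK pathway output, cyclin D1, CCND1 (-1.58), fell and KCNN4 (0.87) rose, and of 17 immediate early genes EGR1 (-1.78) fell, with the same counts adjusted over the list alone. Of 18 cell cycle inhibitors and senescence-associated genes, IGFBP7 (1.66) rose and IGFBP3 (-4.04), LMNB1 (-2.69) and KLF2 (-0.73) fell, with 2 and 3 adjusted over the list alone. These members were named because 5 or fewer of each list passed, after their values were seen. None of the lists passed camera (adjusted p of 0.654, 0.548, 0.514, 0.701 and 0.785). Camera tests whether a list shifts as a whole, and called members of the undifferentiated melanoma, MAPK and cell cycle inhibitor lists moved both ways. That these lists did not pass therefore does not show that senescence or either melanoma state was unchanged. The list of cell cycle inhibitors had a median of 0.14 and a mean of -0.12, and the immediate early list a median of 0.04 and a mean of -0.09, so the median and the mean of each differ in sign, and camera's direction was down for both.

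Of 33 lists tested, 21 passed camera with a preset correlation of 0.01, 7 upward and 14 downward, and 3 passed with an estimated correlation: mitotic genes, DNA replication and S phase, and lysosome and autophagy. By the exact two-sided permutation test of list means, 17 lists reached the smallest p that 4 against 4 can give (0.0286), and the smallest p adjusted over the 33 lists was 0.0555. In other groupings of the 8 arrays camera called up to 20 lists, so the number of lists called by the preset correlation is a weak measure. No other grouping gave any gene past the threshold. Each of them mixes vehicle and doxycycline arrays, however, which widens the residual spread and keeps the count low. The labels call the samples biological replicas without stating that each tumour came from a mouse of its own, and if some shared a mouse the p-values would be too small. No tumours lacking the transgene but given doxycycline were analysed here, so the values compare doxycycline with vehicle, not Omomyc alone.

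**Figure D3:**
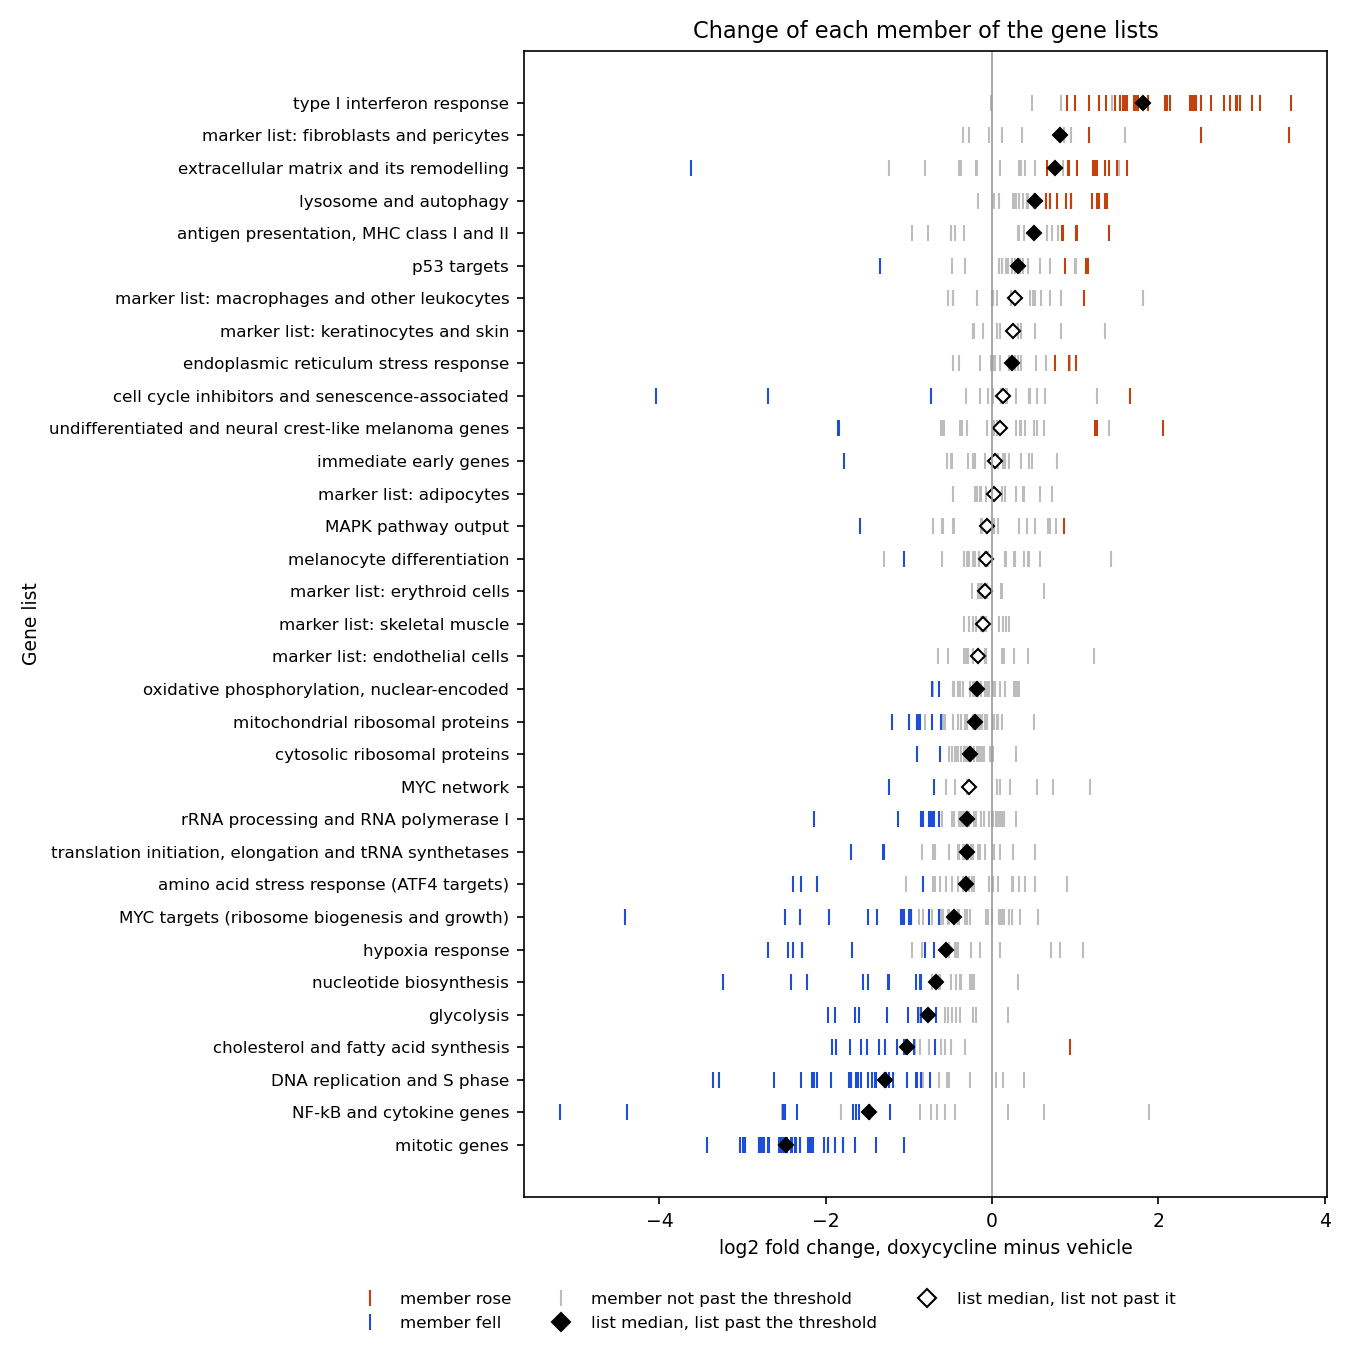
Log2 fold change, doxycycline minus vehicle (horizontal axis), of each measured member of the 33 gene lists (vertical axis), in order of the list median. Ticks are genes, orange for those that rose, blue for those that fell and grey for those not past the threshold, and diamonds are list medians, filled where camera called the list; all 40 mitotic genes lie below 0, around a median of -2.48, and type I interferon genes lie around 1.82.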

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

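Of the tests in this part, those on matched random lists, on scaling, on single tumours, on leukocyte markers and on fibroblast against endothelial markers were chosen after the results were seen; those on groupings of the arrays and on doxycycline itself were set out before.

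Of 288 sets of 4 values tested, 13 (4.51%) held 1 tumour far from the other 3 by Dixon's criterion, about the 1 in 20 that chance gives, and 5 of them concerned vehicle replicate 2. In that tumour CHRNA1 was low at 3.52, with the others at 5.53 to 5.85. TXNL4A (7.83), FAS (5.47) and DGAT2 (5.33) were high in it, and the mean of the lysosome list was low at 7.12. Vehicle replicate 1 was low in the mean of immediate early genes (6.45) and vehicle replicate 3 was high in CTSA (8.69). Among doxycycline tumours, TRAF3 was low (2.74) and MLXIP high (5.67) in replicate 1, and SQLE was high (5.60) in replicate 2. GTF3A was low (4.89) in replicate 3. In doxycycline replicate 4, FAP was high at 10.06, against 8.32 to 8.62 in the others, and MXD3 was low at 4.89.

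Among the 1058 rows without a gene name here, which no comparison of the report uses, 91 passed limma's test when all rows were tested, 34 higher and 57 lower with doxycycline.

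The counts of called genes were set against the 35 ways of splitting the 8 arrays into 4 and 4. The real split gave 1884 genes, 830 upward and 1054 downward, and the highest of the other splits gave 0. The real split was the only 1 as large for each count, 1 in 35, the smallest share that this design allows. Every other split mixes the groups, which widens its residual spread and keeps its count low. The counts of 0 in those splits therefore do not measure how many genes chance alone would call. For gene lists, the real split was also the only 1 as large, with 21 lists, but another split, vehicle replicates 1, 3 and 4 with doxycycline replicate 4 against the rest, gave 20. Splits that keep 3 arrays of a group together still carry part of the group difference, and camera with a preset correlation calls lists in them.

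The mitotic and S-phase lists fell. A lower share of human RNA in the doxycycline tumours would lower other human transcripts of like level as well. The 79 genes of both lists had a median of -1.98, and of 10000 random lists matched on vehicle level the lowest median was -0.27. The 2 lists thus fell further than genes of like level. RMA would partly remove a fall shared by all human transcripts, and the random lists had a median of 0.0097. Their genes were also drawn independently, which narrows the spread of medians. The share of human RNA is therefore not decided by this test. The mitotic median closest to 0 under the 3 scalings tried was -2.23. Relative to all genes it was -2.52, both as deposited and with ribosomal protein centring, since centring moves every gene of an array alike. A shift alike for every gene thus leaves that gap. The quantile step of RMA was not undone, so the scaling between arrays is not decided by these values. Doxycycline acting by itself stays open, because 0 tumours without the transgene but with doxycycline were analysed, and so does induction of Omomyc, which the design names.

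The rise of the type I interferon list may come from more mouse leukocytes or from single tumours. With the leukocyte list mean as a covariate the rise was 1.91 ± 0.70 (SE), against 1.94 ± 0.52 (SE) without it. Only 2 of 20 leukocyte markers lay above the median level of all genes, so the markers are too dim on a human array to decide, and leukocytes cannot be told apart from a change in the tumour cells. With 1 tumour left out the lowest list median was 1.63, which argues against a single tumour making the difference. The spread among vehicle tumours, from 5.88 to 7.78, stays unexplained.

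The rise of fibroblast and matrix lists may come from a lower share of tumour cells, which would raise markers of every other cell type alike. The fibroblast minus endothelial mean was compared in 3 ways, the later ones set after the earlier results were known. Over all markers it differed by 0.92 (log2, exact two-sided permutation p = 0.0286). Over markers bright on average across all arrays it differed by 1.57. POSTN and TAGLN entered that set only through the doxycycline tumours (means of 7.57 and 6.05, against 3.99 and 4.88 in vehicle), so the selection built in part of that difference. Over the 4 fibroblast and 5 endothelial markers bright in vehicle tumours it differed by 1.02 (exact two-sided permutation p = 0.0286). There the fibroblast mean rose by 0.74 and the endothelial mean fell by 0.28 (exact permutation p = 0.143 for the endothelial mean). A lower tumour share still cannot be told apart from a change in fibroblasts or in the tumour cells, because 10 of 15 endothelial markers are dim, the brightest, ENG, reads 9.26 in vehicle tumours, a level that would hide a small host share, and no value measures how much mouse RNA these probes read. The 39 genes of both lists had a median of 0.82, and of 10000 random lists matched on vehicle level the highest median was 0.35. The rise was thus larger than that of genes of like level drawn independently. Such lists had a median of 0.012 on values that RMA had already forced to similar distributions, so they do not decide on the scaling between arrays.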

How the results depend on the processing

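All alternatives were set out before the data were examined, apart from leaving out vehicle replicate 2 and doxycycline replicate 1 together. All 1884 called genes kept their sign under every alternative that kept all the genes. Of the 24 genes with the largest changes, 20 kept their calls under all 17 alternatives, as did 46 of the 58 other list members named and called. Centring arrays on ribosomal protein genes gave 1872 genes higher and 692 lower. It turned the medians of oxidative phosphorylation (0.058), mitochondrial ribosomal proteins (0.037), melanocyte differentiation (0.17), MAPK output (0.18), endothelial (0.077), muscle (0.13) and erythroid markers (0.16), and EGFL7 (0.17), ACTA1 (0.16) and DGAT2 (0.062). The construction of that scaling, which raised the median of all genes to 0.28, accounts for these turns. The fibroblast list lost its call there (adjusted p = 0.0576), although its median was 1.06 against 0.82. Leaving out 1 tumour gave 1252 to 1760 called genes, 503 to 727 higher, 748 to 1057 lower, 19 to 22 lists and a MYC difference of 0.87 to 1.62, with fewer samples in each fit. MYC passed at 1.42 with ribosomal protein centring, 1.28 with array weights and 1.55 without both tumours. With an estimated correlation 3 lists passed, and by fry 23. The p53 list lost its call without the dimmest genes (adjusted p = 0.0524) and by fry (adjusted p = 0.125), and fry alone called the MYC network, cell cycle inhibitors (adjusted p = 0.0389 for each) and undifferentiated melanoma genes (adjusted p = 0.0484). The other reversals were of values that had not passed, and their cause was not tested. Immediate early genes went to -0.0067 and adipocyte markers to -0.18 without the dimmest genes, and melanocyte genes to 0.029 with array weights. With tumours left out, the medians ranged from -0.16 to 0.10 for melanocyte genes, from -0.093 to 0.040 for immediate early genes, from -0.054 to 0.079 for adipocyte markers, from -0.15 to 0.019 for erythroid markers and from -0.30 to 0.022 for endothelial markers. Likewise DGAT2 ranged from -0.37 to 0.15, MLXIPL from -0.013 to 0.34, MNT from -0.098 to 0.35, MLX from -0.015 to 0.18, EGFL7 from -0.19 to 0.029, ACTA1 from -0.16 to 0.0014 and FAP from -0.042 to 0.59. With the replicate number as a block, 1293 genes passed, 502 higher and 791 lower, and 21 lists. Deviations of tumours with the same number correlated at -0.16 to 0.03 across genes, those with different numbers at -0.09 to 0.23, and no vehicle tumour correlated best with its own number, so the numbers show no pairing. Without background values the limit that dim signal sets is unknown.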

Other observations

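Gene families below were picked after seeing the data, 10 in all, and are adjusted together. Of 55 replication-dependent histone genes measured, 40 fell and none rose, with a median log2 fold change of -1.57. H2BC14, H1-5, H3C2 and H2AC14 fell by 3.22, by 2.98, by 2.75 and by 2.75. Many histone genes share sequence, so single members are uncertain. The spliceosome's snRNP proteins (22 measured, 9 fell, median -0.55), the chaperonin CCT (7 measured, with CCT2, CCT5 and CCT8 lower, median -0.52), nucleoporins (20 measured, 2 fell, median -0.40) and proteasome subunits (36 measured, 4 fell, median -0.22) had no member that rose. Camera called these 5 families (adjusted p of 2.1e-35, 3.8e-06, 0.000500, 0.000721 and 0.00298), and none with an estimated correlation (adjusted p = 0.0574, adjusted p = 0.0786, adjusted p = 0.123, adjusted p = 0.133 and adjusted p = 0.0786 with an estimated correlation).

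Of 11 measured genes of neutrophil chemokines, interleukin 1, IL6 and CSF3, 8 fell and none rose, with a median of -2.35, including CXCL1 (-2.51) and CXCL6 (-1.14). CXCL1, CXCL2, CXCL3, CXCL8, IL1A, IL1B and IL6 also belong to the NF-kB and cytokine list, and CXCL5 is among the largest falls. The family thus largely repeats results given above. Camera called this family (adjusted p = 1.2e-07), but not with an estimated correlation (adjusted p = 0.123 with an estimated correlation). Adjusting over the picked families does not correct for picking them after seeing the data. The family mean was 8.47 in vehicle replicate 2, against 6.82 to 7.39 in the other vehicle tumours. Doxycycline replicate 4 was at 6.47, against 4.52 to 5.13 in the other doxycycline tumours. Of 10 interferon gamma-inducible chemokines and GTPases measured, GBP3 rose by 1.04, and the list mean was 7.80 in vehicle replicate 2, above every doxycycline tumour (5.78 to 6.84), and 4.18 to 4.97 in the other vehicle tumours. CXCL10 read 10.08 in vehicle replicate 2 and 1.58, 1.71 and 5.17 in the other vehicle tumours. Camera called the family (adjusted p = 0.0284), but not with an estimated correlation (adjusted p = 0.559 with an estimated correlation).

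Among 34 ABC transporters 4 rose and 4 fell, with ABCA1, a cholesterol exporter, 2.64 ± 0.26 (SE) higher and ABCA7 1.81 ± 0.30 (SE) higher, and ABCB10, ABCB9 and ABCG2 lower by limma (log2 fold changes of -1.85, -1.13 and -1.32). The family did not pass camera (adjusted p = 0.917). Of 481 genes named ZNF, 16 rose and 11 fell, with a median of 0.14, called by camera (adjusted p = 0.0392) but not with an estimated correlation (adjusted p = 0.516 with an estimated correlation). Of 346 olfactory receptor genes, which this tissue should hardly express, 1 rose, with a median of 0.03 (camera adjusted p = 0.928).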
